A study of Mus musculus with 2 samples.

How the data were processed

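Left cerebral cortex of B6CASTF1/J hybrid mice, 18 to 20 months old, gave 2 microRNA sequencing libraries of RNA under 30 nt. The labels number them as biological replicates 1 and 2 with separate tissue sample records that point to 1 shared donor record, so it stayed open whether the tissue came from separate animals, and the spread between the libraries may be partly technical. The sample fields call the mice male while the free-text description calls them female. This conflict was left open and sex was not used.

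For each library the authors deposited a table of whole-number read counts per miRNA gene, without normalization. Per the notes deposited beside each table, the genome build was mm10 and the annotation GENCODE M21. The aligner, its settings and any adapter trimming are not given in the sources used here. Each deposited table has 4 leading lines for unmapped, multimapping, no-feature and ambiguous reads, then count columns for both strands together, the gene's strand and the opposite strand, a layout like that of STAR's gene-count output. Reads that map to several places stand on their own line and not under a gene: 35.6% of reads in replicate 1 and 44.8% in replicate 2. The column of the gene's strand was taken as sense from the values, since the other stranded column was filled almost only at genes overlapped by a miRNA gene on the other strand (64 loci have one). The summary lines were kept out of library sizes and tests.

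All 2202 gene identifiers matched the GENCODE M21 annotation, which gave symbols, coordinates (counted from 1) and surrounding genes. Hairpin GC content and length came from the annotated transcripts. Shared words of 20 bases were searched among the annotated transcripts of genes that do not overlap the hairpin, on both strands. No genome sequence and no annotation of mature miRNA arms was used here, so a count stands for a whole hairpin and copies outside annotated transcripts were not searched.

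Counts were scaled to CPM, with the sense reads at miRNA genes as the library total. Log values used a pseudocount of 1 CPM. Effective library sizes used TMM in edgeR 4.0.16 (R 4.3.3), with factors 0.9905 and 1.01. The common dispersion came from an intercept-only design over genes with at least 10 reads in each library. The libraries were compared per gene by a two-sided exact binomial test given the effective library sizes, over genes with at least 10 reads in total, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors written "counting SE" cover counting noise alone. Permutation tests across genes or pairs drew 100000 resamples, and list medians were set against 10000 random lists matched on mean CPM. Alternative RLE size factors came from edgeR, and DESeq2 1.42.0 gave an alternative median dispersion. Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 was used for the rest. With 1 group, no quasi-likelihood test between groups exists.

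The tests, the 17 miRNA lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from the alternatives and tests that the closing parts name as chosen later. The minimum of 10 reads in total for neighbouring genes was also set later. List members were matched by gene symbol. The planned names Mir92a, Mir146a and Mir3070 matched no symbol, so Mir92-1, Mir92-2, Mir146, Mir3070a and Mir3070b were left out of the lists. For the list median ratios, library totals were the scaling named beforehand, with TMM as an alternative. TMM was used instead, and library totals are the alternative. Named are the 15 genes of highest mean CPM, up to 4 members of each list with the highest mean CPM, the 10 largest ratios among genes past the binomial test with a mean of at least 100 CPM, and all loci of the miR-9, miR-124, miR-128, miR-138, miR-218 and miR-29b stems. Partner genes on the opposite strand, Mir26a-2, Mir134 and Mir485 are named as well, chosen after their values were seen.

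The binomial test was tested on simulated data with the means and library sizes of these 472 genes: with counting noise only and no spread between replicates, it called 1.1% of 272 unchanged genes and 44%, 66%, 84% and 100% of 50 genes each that were changed 1.5-, 2-, 4- and 8-fold. The dispersion estimate, tested on simulated data of 367 genes, gave coefficients of variation of 0.192 for a true 0.2 and 0.391 for a true 0.4.

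Alternatives covered both-strand counts, other read minimums, pseudocounts, size factors, dispersion estimates, word lengths and distances, and each library alone. Counts of loci that share sequence with another locus, 11.1% of sense reads in replicate 1 and 11.7% in replicate 2, are uncertain, because reads of such copies can be left out of the gene counts.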

Results

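Small RNA of under 30 nt was sequenced from the left cerebral cortex of aged mice, 18 to 20 months old, of the B6CASTF1/J hybrid, the first-generation cross of the C57BL/6J and CAST/EiJ strains. The labels give 1 group of 2 biological replicates, so the comparisons lie between genes and between the 2 libraries, and none lies between conditions. Replicate 1 held 8041772 reads and replicate 2 held 12239366. Reads on the annotated strand of a microRNA (miRNA) gene numbered 2381663 in replicate 1, which was 29.6% of its reads (95% exact binomial interval 29.58 to 29.65), and 4436398 in replicate 2, which was 36.2% (36.22 to 36.27). Unmapped reads made up 30.8% and 14.6% of the 2 libraries, and reads on the no-feature line 4.01% and 4.38%. Multimapping reads stand on a line of their own, so the no-feature shares leave out any of them that lie outside miRNA genes. A count of 0 allowed a level of up to 1.26 CPM (reads of a gene scaled to the total of sense miRNA reads in its library) in replicate 1 and 0.676 CPM in replicate 2. These intervals and limits cover counting error only, since reads amplified by PCR are not independent molecules.

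The let-7 family, which restrains growth-promoting transcripts in differentiated cells, and miR-139 had the most reads among those assigned to a miRNA gene. Multimapping reads, 1.20 and 1.24 per assigned sense read in replicates 1 and 2, stand under no gene, so the order of abundance leaves them out. Mirlet7g reached 109501 ± 8613 CPM (SD, n = 2) and Mir139 reached 108195 ± 11051 CPM, so their order was not distinguishable beyond the spread between replicates. Mirlet7b followed at 76034 ± 9863 CPM, then Mir132, an activity-regulated miRNA of neurons, at 56498 ± 18595 CPM. Mirlet7i at 51219 ± 5432 CPM and Mirlet7e at 36976 ± 2247 CPM came next. The imprinted Mir127 stood at 35059 ± 9856 CPM, Mirlet7d at 31962 ± 18454 CPM, Mir744 at 29211 ± 1336 CPM and Mir29a at 22318 ± 5144 CPM. Mir125a, Mir23b, Mir126a, Mir128-1 and Mir652 completed the 15 most abundant genes, with means from 20834 CPM for Mir125a down to 12573 CPM for Mir652. The 10 most abundant genes of each library took 56.5% of its miRNA reads in replicate 1 (95% exact binomial interval 56.45 to 56.58) and 55.9% in replicate 2 (55.82 to 55.91), a mean of 56.2% ± 0.46 (SD, n = 2), and 9 of these genes were shared by both libraries.

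Most of the leading loci lay within longer transcripts of the annotation (mm10, GENCODE M21). Mirlet7g (ENSMUSG00000065440.1) lies at chromosome 9, 106178840 to 106178927, plus strand, in an intron of Wdr82, and Mir139 (ENSMUSG00000065446.1) at chromosome 7, 101475376 to 101475443, plus strand, in an intron of Gm45837. Mirlet7b (ENSMUSG00000065564.1) lies at chromosome 15, 85707319 to 85707403, plus strand, in an exon of the noncoding Lncppara. Mir132 (ENSMUSG00000065537.2) lies at chromosome 11, 75173682 to 75173747, plus strand, in an intron of the noncoding 1700016P03Rik. Mir29a (ENSMUSG00000065610.1) lies at chromosome 6, 31062660 to 31062747, minus strand, where no gene of a type other than miRNA contains it on its strand.

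Of 2202 annotated miRNA genes, 367 had at least 10 reads in each library, 728 had a read in at least 1 library and 1474 had none. A mean of 1000 CPM or more was reached by 95 genes, and 10000 CPM or more by 19.

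Lists of miRNAs tied to cell types or gene clusters were compared by their summed level. The let-7 list of 12 loci held 33.1% of miRNA reads in replicate 1 and 29.9% in replicate 2. The neuron list of 19 loci summed to 109733 ± 10025 CPM (SD, n = 2), led by Mir132 and Mir128-1 (16709 ± 3331 CPM), with Mir330 at 9420 ± 2450 CPM and Mir383 at 6661 ± 496 CPM. The 3 loci of miR-9, a miRNA of neural progenitors and neurons, summed to 67.7 ± 3.71 CPM, and all 3 share sequence with another gene. The listed loci of the imprinted Dlk1-Dio3 cluster of chromosome 12, expressed from the maternal chromosome, summed to 99735 ± 3803 CPM. Of these 50 loci, 44 had at least 10 reads in each library. Mir3070a and Mir3070b were planned but not matched, so the list need not hold every locus of the cluster. The leading members of this list were Mir127, Mir433 at 9847 ± 1537 CPM, Mir411 at 7724 ± 2527 CPM and Mir382 at 6550 ± 1217 CPM. Mir134 and Mir485 belong to both the neuron list and this cluster.

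Lists of glia and vessels lay below the let-7, neuron and Dlk1-Dio3 lists and above the miR-9 list at 67.7 CPM. Loci that share sequence with another gene, whose reads can be left out, were unevenly spread over the lists. They were 11 of 19 neuron, 6 of 12 let-7 and 6 of 50 Dlk1-Dio3 loci. Among glia and vessels they were 6 of 8 astrocyte, 4 of 5 oligodendrocyte, 3 of 7 mural and 0 of 2 endothelial loci. The order of the sums need not be that of the cell types. The astrocyte-associated list summed to 43457 ± 5131 CPM, led by Mir29a, with Mir23a at 10909 ± 1427 CPM, Mir26b at 7836 ± 1089 CPM and Mir29c at 2029 ± 256 CPM. Endothelium was represented by Mir126a, in an exon of Egfl7, at 17573 ± 799.7 CPM. Mural cells, the smooth muscle cells and pericytes of vessels, were represented by Mir143 at 7938 ± 3522 CPM, Mir145a at 349 ± 110 CPM and Mir214 at 76.97 ± 4.95 CPM, while Mir199b had 1 read in replicate 1 and 3 in replicate 2. The oligodendrocyte list summed to 4093 ± 836 CPM, carried by Mir338 at 2428 ± 919 CPM and Mir219a-2 at 1659 ± 83.4 CPM, with Mir219a-1 at 5.98 ± 0.147 CPM and a single read for Mir219b. With both strands counted together, which drops reads where miRNA genes overlap on opposite strands, the oligodendrocyte list stood at 0 CPM, the endothelial list at 0.229 CPM and the erythroid list at 20.7 CPM. The myeloid and lymphoid list summed to 1889.7 ± 28.2 CPM, most of it Mir150, a lymphocyte miRNA, at 1735 ± 48.01 CPM. Mir146, at 749 CPM in replicate 1 and 707 CPM in replicate 2, was planned for this list but not matched, so the sum leaves it out. Mir142, found in all blood lineages, stood at 99.6 ± 71.1 CPM, Mir155 at 40.8 ± 1.64 CPM and Mir223, of neutrophils and monocytes, at 13.9 ± 3.45 CPM.

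The list reported to move with age or inflammation summed to 15135 ± 212 CPM, with Mir22 at 9333 ± 2669 CPM, Mir34a, a target of p53, at 3112 ± 90.6 CPM, and Mir21a at 2650 ± 2546 CPM. Mir155 is on this list as well as the myeloid one. Mir146 was planned for both lists but not matched, so both sums leave it out. No young cortex was measured, so these levels carry no comparison with age. The list of the miR-17-92 cluster and its paralogs summed to 1942 ± 266 CPM. Its leading members were Mir93 at 1113 ± 156 CPM, Mir106b at 339 ± 50.5 CPM, Mir17 at 301 ± 47.1 CPM and Mir20a at 106 ± 8.07 CPM. This sum and order leave out Mir92-1, at 278 CPM in replicate 1 and 483 CPM in replicate 2, and Mir92-2, at 16.8 and 18.9 CPM. Both were planned for the list but not matched.

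Lists of tissues next to the cortex, or far from it, had these levels. The choroid plexus and ciliated cell list summed to 917 ± 242 CPM, with Mir204 at 626 ± 60.9 CPM, Mir34c at 245 ± 175 CPM, Mir449a at 30.2 ± 4.17 CPM and Mir34b at 10.4 ± 4.24 CPM. The epithelium, olfactory bulb and pituitary list summed to 399 ± 20.2 CPM, with Mir375 at 264 ± 7.95 CPM, Mir429 at 36.45 ± 7.24 CPM, Mir200b at 29.7 ± 23.6 CPM and Mir194-2 at 24.2 ± 4.6 CPM. The erythroid list summed to 82.6 ± 21.5 CPM, with Mir451a at 36.3 ± 19.4 CPM, Mir486 at 27.4 ± 0.147 CPM and Mir144 at 18.97 ± 2.28 CPM. Mir122, the main miRNA of hepatocytes, stood at 67.2 ± 12.4 CPM. The muscle list summed to 28.4 ± 1.34 CPM, with Mir206 at 16.6 ± 3.29 CPM, Mir499 at 8.92 ± 4.01 CPM, Mir1b at 2.15 ± 1.12 CPM and Mir208a at 0.548 ± 0.181 CPM. The embryonic stem cell list summed to 1.40 ± 0.391 CPM, with no read at 12 of its 14 loci and only 1 to 4 reads per library at Mir302b and Mir302d.

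**Figure D1:**
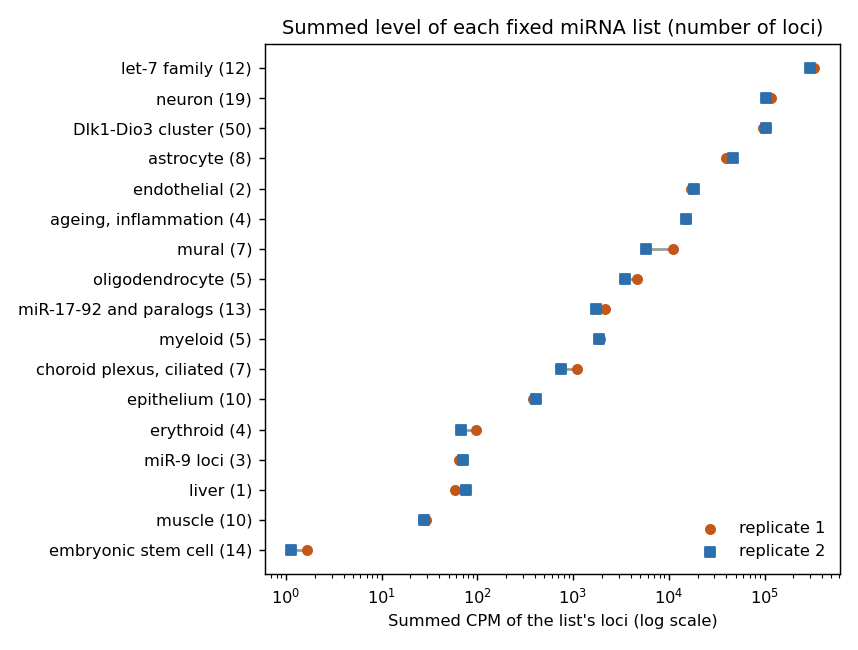
Summed CPM (log axis) of the loci of each of 17 miRNA lists in replicate 1 (circles) and replicate 2 (squares), with the number of loci in parentheses. The let-7 list is highest, at 330763 and 299462 CPM, and the embryonic stem cell list lowest, at 1.68 and 1.13 CPM.

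The replicates were compared gene by gene to see how far their miRNA profiles differed. The largest ratios among genes of at least 100 mean CPM belonged to Mir26a-1, in an intron of Ctdspl, and Mir301, in an intron of Ska2. Mir26a-1 had 540 reads in replicate 1 and 43 in replicate 2, a log2 ratio of 4.44 ± 0.23 (counting SE). Mir301 had 64 and 1106 reads, a log2 ratio of -3.14 ± 0.18. Mir21a, an miRNA induced in inflammation and injury, was higher in replicate 1 by 2.42 ± 0.03 on the log2 scale, and Mir99b was lower there by a log2 ratio of -2.06 ± 0.02. Mir101b (log2 ratio 2.04), Mir135b (1.93), Mir376c (1.85), Mir222 (1.82), Mir34c (1.62) and Mir136 (1.57) were all higher in replicate 1. The hairpins of Mir101b and Mir376c share a word of 20 bases with another gene, so their reads are uncertain.

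Across 472 genes with at least 10 reads in total, Pearson's r of log2(CPM + 1) was 0.981 and Spearman's rho 0.968, both across genes, which are not independent replicates. An exact binomial test, two-sided with Benjamini-Hochberg adjustment, allows for counting noise alone and compares the libraries, not conditions. It called 246 of the 472 genes (52.1%), of which 116 were higher in replicate 1 and 130 in replicate 2. With RLE size factors the majority turned, with 53.1% of 241 called genes higher in replicate 1 and 113 genes higher in replicate 2. Of the 246 genes called with TMM, the difference reached 1.5-fold for 133, 2-fold for 64 and 4-fold for 7. The chi-square over genes was 442 per degree of freedom, so the libraries differed by far more than sampling noise. The common biological coefficient of variation in edgeR was 0.342 over 367 genes. edgeR's exact test, with a common dispersion estimated again over the 472 genes, called far fewer genes than the binomial test. It ranked Mir26a-1 (edgeR log2 ratio 4.57) and Mir301 (-3.18) first. It sets 1 library against 1, with a dispersion from these same 2 libraries, so it gives no replicate evidence for any gene. Mir26a-1 also shares sequence with Mir26a-2, so its reads are uncertain.

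**Figure D2:**
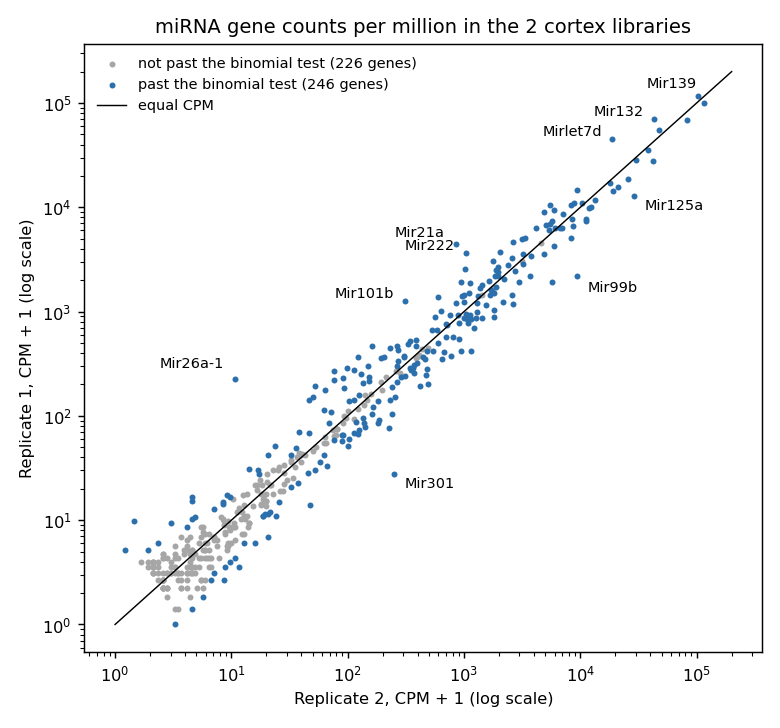
CPM + 1 of 472 miRNA genes in replicate 2 (horizontal, log axis) and replicate 1 (vertical, log axis); blue points passed the exact binomial test of the libraries (246 genes), grey points did not (226), and the line marks equal CPM. Mir26a-1 and Mir301 lie far from the line on opposite sides.

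The binomial test was also counted within each list. It allows for counting noise alone, so abundant loci pass it at small differences, and far fewer genes pass when the spread between the libraries is allowed for. In the let-7 list 11 of 12 tested loci passed the binomial test, 8 of them higher in replicate 1, and 11 passed when adjusted over the list alone. In the Dlk1-Dio3 cluster 37 of 45 passed, 16 higher in replicate 1 and 21 in replicate 2, and 37 when adjusted over the list alone. In the neuron list 14 of 16 passed, 5 higher in replicate 1 and 9 in replicate 2, and 14 when adjusted over the list alone. All 8 astrocyte loci passed, 4 in each direction, and 8 when adjusted over the list alone. Of the mural list 2 of 3 passed, Mir143 (log2 ratio 0.97) and Mir145a (0.68), both higher in replicate 1, and 2 when adjusted over the list alone. The epithelium list had 3 of 9 past the test and 2 when adjusted over the list alone. For the other lists the count was the same under both adjustments: 3 of 9 for the miR-17-92 list, 3 of 5 for the choroid plexus and ciliated list, 2 of 4 for the ageing and inflammation list, 2 of 3 for the oligodendrocyte list, 1 of 4 for the myeloid list, 1 of 3 each for the erythroid and muscle lists, 1 of 1 each for Mir126a and Mir122, and 0 of 3 for miR-9. No locus of the embryonic stem cell list had enough reads to be tested. These counts and the medians leave out unmatched genes. Of those, Mir92-1 passed the binomial test higher in replicate 2 (log2 ratio -0.77) and Mir146 higher in replicate 1 (0.11). Set against 10000 random lists matched on mean CPM, the median log2 ratio lay at the 94.4th percentile for the mural list (0.68), the 95.2nd for the muscle list (0.76) and the 8.89th for the Dlk1-Dio3 cluster (-0.16). The muscle median was the value of Mir1b, with 7 reads in replicate 1 and 6 in replicate 2 (log2 ratio 0.76 ± 0.80, counting SE). With both strands counted together the medians of the muscle list and the Dlk1-Dio3 cluster were 0, and a locus left without reads has a ratio of 0. All other tested lists lay between the 16.6th percentile of the neuron list and the 90.7th of the miR-17-92 list.

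miRNAs with several genomic copies were compared with single-copy ones. miR-124, the hallmark miRNA of neurons, was almost uncounted: Mir124a-1 had 2 and 4 reads in replicates 1 and 2, Mir124a-2 had 2 and 2, and Mir124a-3 had 3 and 0. Mir9-3 had 118 and 231 reads, Mir9-1 had 32 and 76, and Mir9-2 had 5 and 5. Other copies were counted in large numbers, with Mir128-1 at 16709 CPM, Mir128-2 at 3027 ± 223 CPM, Mir138-1 at 2934 ± 1048 CPM and Mir138-2 at 1701 ± 664 CPM. Mir218-2 stood at 132 ± 8.00 CPM, Mir29b-2 at 109 ± 45.1 CPM, Mir29b-1 at 79.98 ± 29.4 CPM and Mir218-1 at 21.7 ± 5.08 CPM. Over the lists, the 55 loci whose hairpin shares a word of 20 bases with another annotated gene had a median log2(mean CPM + 1) of 4.66, and the 116 without one had 7.23. The difference of -2.57 did not pass a two-sided permutation test across loci (p = 0.0591). Words of 18 or 22 bases gave differences of -0.71 (permutation p = 0.698) and -1.12 (permutation p = 0.518), and copies taken from the gene symbol gave -1.12 (permutation p = 0.536). Over all annotated loci, a set chosen after the list result was seen, 179 of 1265 sharing loci (14.2%) and 549 of 937 others (58.6%) had a read. The median difference was -0.51 (permutation p = 1e-05, the smallest the resamples can give). Only 362 of the 1265 sharing loci carry a Mir symbol, so this contrast is not mainly one of copies of named miRNAs. Among loci with a Mir symbol, also chosen later, 156 of 362 sharing loci (43.1%) and 526 of 812 others (64.8%) had a read. There the median difference was -0.75 (permutation p = 6e-05). Among all loci with at least 1 read, a filter on the measured level itself, the difference was 1.28 (permutation p = 0.00665).

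**Figure D3:**
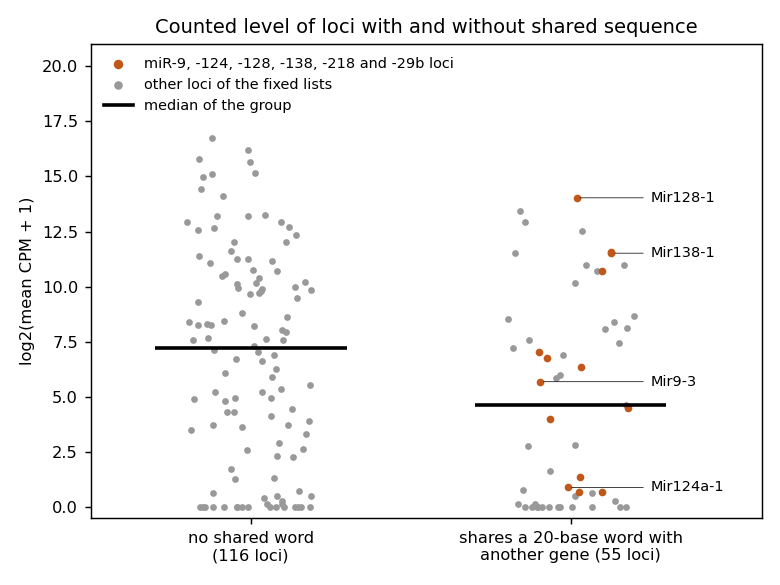
log2(mean CPM + 1) of the list loci that share no word of 20 bases with another gene (116 loci) and of those that do (55 loci), with 1 point per locus, bars at the group medians of 7.23 and 4.66, and the named multi-copy loci in orange. Mir128-1 lies at the top of the sharing group and the Mir124a loci near 0.

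miRNA genes that lie close together had more similar levels than shuffled genes. Among 110 pairs of neighbours within 10 kb on the same strand, the mean absolute difference in log2(mean CPM + 1) was 2.99, against 4.06 when the levels were shuffled among the same genes, which is 73.7% of the shuffled value. The one-sided permutation p was 1e-05, the smallest that 100000 resamples can give. Over all annotated genes, where a pair without reads counts as equal, 353 pairs differed by 43.96% of the shuffled value. Mir106b and Mir93, in Mcm7 on chromosome 5, Mir17 and Mir20a, in Mir17hg on chromosome 14, and Mir143 and Mir145a on chromosome 18 are such neighbours. The last of these lie far apart in level, at 7938 and 349 CPM.

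Counts on the strand opposite to a miRNA gene made up 7.66% of all sense and antisense counts in replicate 1 (95% exact binomial interval 7.63 to 7.69) and 7.98% in replicate 2 (7.96 to 8.01). In replicate 1, 99.96% of these counts lay at genes with an annotated miRNA gene on the other strand. There a read counts as sense for 1 gene and as antisense for its partner. The share and its interval thus count such reads 2 times and do not measure antisense RNA. With both strands together, 197474 reads of replicate 1 were ambiguous, the same number as its antisense counts at such genes. Antisense reads at other genes numbered 84 in replicate 1 and 145 in replicate 2. The antisense count of Mir126b was 40505 and 80469 reads in the 2 libraries and the sense count of its partner Mir126a was 40506 and 80469, a match to within 1 read. Gm25927 and Mirlet7e formed a like pair, with 84282 reads in replicate 1 and 171090 in replicate 2 under both genes, and so did Mir3065 and Mir338, with 7332 and 7889.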

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

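The test of multi-copy loci was planned, and the alternatives without the muscle, liver and embryonic stem cell lists and over all annotated loci were chosen only after its result was seen.

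Reads that map to several places were not used in any comparison, yet they outnumbered the sense reads of miRNA genes in both libraries, with 1.20 such reads per sense read in replicate 1 and 1.24 in replicate 2. They are listed here as reads outside the main measurement. Being above the limit of 3 counts was certain for a whole class of reads and carries no weight. A technical hypothesis is that multi-copy miRNAs, such as miR-124 and miR-9, are counted low because their reads are left out of the gene counts. The list loci that share a word lay lower by a median log2 difference of -2.57 (permutation p = 0.0591), and the bound set before the result counted any p of 0.05 or more against this explanation. That bound was set aside after the result was seen, and the explanation read as open, because a p that misses the threshold does not exclude a difference of -2.57 and a shared word need not lie in the mature arm. Among planned definitions of a copy, words of 18 bases gave -0.71 (permutation p = 0.698), words of 22 bases -1.12 (p = 0.518) and gene symbols -1.12 (p = 0.536), while without the muscle, liver and embryonic stem cell lists the difference was -1.46 (permutation p = 0.128), and over annotated loci with a Mir symbol, of which 43.1% of those sharing a word and 64.8% of the others had a read, it was -0.75 (permutation p = 6e-05), though loci that are silent in cortex lower these shares too. The multimapping reads are not assigned to loci in the tables used here, which keeps this open, and no biological explanation was tested, since the design has 1 group.

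Antisense reads at genes with no miRNA gene on the opposite strand numbered 84 in replicate 1 and 145 in replicate 2. They are listed as reads outside the main measurement, and as a sum over many genes they would pass the limit of 3 counts for a single count of 0 with very few reads per gene.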

How the results depend on the processing

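The alternatives that take out the GC trend, use all annotated genes for neighbours, use only loci with no shared word, leave out 3 lists or test all annotated loci for shared words were chosen after seeing the data, as was TMM in place of library totals for the list median ratios. With both strands counted together, 9 list levels stayed within the spread between replicates and 8 moved. Using 1 library alone cannot move a mean of 2 beyond their SD, so it says nothing on list levels or the top-10 share. List median ratios stayed within their standard error in 40 alternatives and moved in 2, the muscle list and the Dlk1-Dio3 cluster with both strands, both to 0. The both-strand medians of the oligodendrocyte, erythroid and miR-9 lists were also 0 and were counted as staying. A locus that loses all its reads has a ratio of 0, so these medians cannot show agreement. Of 19 alternatives for counts of genes and the coefficient of variation, 17 stayed within 1.5 times. The multi-copy and neighbour tests kept their direction and side of the threshold in 13, though the size ran from -0.71 to -2.94 for the former and from 75.8% of shuffled down to 43.96% over all annotated genes for the latter. Counting both strands together, which drops reads where hairpins overlap on opposite strands, took the oligodendrocyte list to 0 CPM, the endothelial list to 0.229, the erythroid list to 20.7 and miR-9 to 57.4. The myeloid list stood at 1956, the epithelium list at 436, the ageing and inflammation list at 16538 and the Dlk1-Dio3 cluster at 104036 CPM, all higher than with sense counts. The dropped reads also lower the total used for CPM, from 2381663 to 2184273 reads in replicate 1 and from 4436398 to 4051808 in replicate 2. A list whose reads stay the same thus rises in CPM, and these rises need not be gains in reads. Counting both strands together also gave a top-10 share of 59.4%. Asking for 1 read in each library gave 580 detected genes, by construction. Pearson's r was 0.976 and 0.985 with pseudocounts of 0.1 and 10, and 0.969 over genes with 100 reads in total; the cause was not tested. edgeR's exact test called far fewer genes than the binomial test because it adds the spread between the libraries. Over all annotated loci the multi-copy difference was -0.51, and -0.75 over those with a Mir symbol, both past the threshold. Over loci with a read it was 1.28, reversed, a filter that drops 1086 of the 1265 sharing loci and 388 of the 937 others for having no read. Without the 10 genes with the most antisense reads the antisense share, which counts reads of overlapping genes under both, was 0.365%. Each replicate alone gave 372 to 426 detected genes and multi-copy differences from -2.94 to -2.02. Depth limits genes under 10 reads, and the spread rests on 2 libraries.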

Other observations

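The tests of GC content and of transcription units were chosen only after the difference between the libraries was seen, and the clusters and copies in the next paragraph were picked after their values were seen; the test of neighbours was planned.

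Members of some clusters differed in their ratio between the libraries and members of others lay close. On chromosome 17, within Spaca6, Mir99b had a log2 ratio of replicate 1 over replicate 2 of -2.06, Mir125a of -1.14 and Mirlet7e, which lies between them, of -0.10. On chromosome X, Mir221 had a log2 ratio of 0.94 (21562 and 21411 reads) and Mir222 of 1.82 (8597 and 4629 reads). In Mcm7 on chromosome 5, Mir106b had a log2 ratio of 0.33 and Mir93 of 0.31, and in Mir17hg on chromosome 14, Mir17 had 0.35 and Mir20a 0.18. Mir26a-1, in Ctdspl on chromosome 9, had 540 and 43 reads, while Mir26a-2 on chromosome 10 had 161 and 203 reads.

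Neighbouring loci had closer levels than shuffled pairs (permutation p = 1e-05, the smallest the resamples can give), which is consistent with the hypothesis that neighbours are processed from 1 transcript. The test was planned and could have come out the other way. Shared sequence between duplicated neighbours was not separated from it, and no biological explanation beyond the shared transcript was tested.

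The miRNA levels of the libraries differed by more than counting noise. Hairpin GC content as the whole cause is argued against, since the coefficient of variation was still 0.327 after a linear GC trend was taken out, against 0.342 before, but GC may be a part of it: across 367 genes, which are not independent replicates, Spearman's rho of GC with the log2 ratio was -0.319 (permutation p = 1e-05, adjusted 1.3e-05 over 4 gene sets), and the median ratio went from 0.34 in the 92 genes of lowest GC to -0.21 in the 92 of highest. Transcription units that differ between the samples, as the whole cause, are argued against by neighbours with at least 100 reads in each library. Their log2 ratios differed by 96.1% of the shuffled value (bootstrap 79.95 to 113, permutation p = 0.282). The mean difference was 0.78, against 0.07 expected from counting noise alone. The bounds of this test were rewritten after a first version at 10 reads had given 93.8% (permutation p = 0.144), so meeting them carries no weight of its own. The 73 pairs hold 104 genes, so pairs share genes and the bootstrap interval can be too narrow. A difference between the tissue samples or in library preparation stays open and untested.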
